A study of Mus musculus with 6 samples.

How the data were processed

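In situ Hi-C was made from 150000 LSK cells per library with a proximity-ligation kit, per the labels' protocols. DNA was sheared to about 400 bp and sequenced as 150 bp paired ends. The labels state the same approximate read number for every library and no count per library, so the depth of each sample is not known here. The 6 samples were of the same mixed strain background, came from batch 1, and all animals received poly(I:C) at 2 ug per g body weight, per the labels. Control cells were sorted as LSK cells, while NICD and NICD/Tcf7-KO cells were sorted as CD45.2-positive, eGFP-positive LSK cells, so the gate differs between control and the other conditions and cannot be separated from genotype. The labels describe the third condition as Tcf7 knock-out in the title and as knocked down in the design text.

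The series gives 69 files used here, 66 loop lists and 3 domain lists. Each was made for a whole condition with its 2 replicates combined, per the labels' design text, so that values per replicate were not analysed here. Contact matrices were not analysed here. Maps were built on mm10 with Juicer 1.6, per the submitters' processing notes, and the lists carry the mark of juicer_tools 1.22.01, per the file headers. The loop lists have the layout of HiCCUPS and the domain lists that of Arrowhead. Aligner settings and contact filters are not given in the sources used here. Loops were called at 22 bin sizes, at 2.5 kb and from 5 to 25 kb in steps of 1 kb. Each row of a loop list holds the observed contact count, which is a whole-number count deposited without normalization, per the file headers. It also holds 4 expected values, a signal the authors computed from the surroundings of the pixel (donut, lower-left, horizontal and vertical), and a q-value against each, per the file headers. In the lists the lowest observed over donut-expected value was 1.75 and the highest q-value 0.100, as tested on the files. The domain lists hold a corner score per domain, deposited by the authors without a fixed range, at 5 kb bins.

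The 10 kb list of each condition was the main list. Loops of different conditions were matched when both anchor midpoints lay within 20 kb, and chance was taken from 100 circular shifts along each chromosome. As there were no replicate lists, the same condition called at 9 and 11 kb served as the technical reference. A loop was called particular to a condition when no list of the other condition, at any of the 22 bin sizes, held a loop within 20 kb (or within 1 bin where the bin is wider) at both anchors. Strength was the observed over the donut-expected count, compared at mutually nearest shared loops, with exact intervals on the ratio of counts that hold the expected values fixed. Medians have intervals from resampling loops, and shares have exact Clopper-Pearson binomial intervals. PCR duplicates and pooling of animals are outside such intervals, which cover counting error or sampling of loops only. Unchanged counts were drawn from Poisson distributions 100 times. Domain ends were merged within 10 kb and matched within 25 kb. Contact ratios per chromosome are medians over shared loops. For the presence of loops in 3 conditions, the 10 kb lists were merged within 20 kb into a common list, and each of its loops counted as present in a condition that called it within the same distance at any of the 22 bin sizes. This common list counts more loops as held by NICD than the 10 kb list of NICD alone does.

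Genes came from the RefSeq table of GRCm38.p6, which has the mm10 coordinates, with 21887 protein-coding genes. The table has no strand, so a gene was placed at a loop when either of its ends, not its start site alone, lay within 5 kb of an anchor. This departs from the planned use of start sites. Of 182 genes in 10 lists fixed before the data were examined, 180 were found as protein-coding, and Mx1 and Mx2 are listed as transcribed pseudogenes and were left out. The lists are Notch targets, T-lineage, stem and progenitor, myeloid and erythroid-megakaryocyte, B-lineage, Wnt pathway, cell cycle, T-cell leukaemia, chromatin architecture and interferon response genes. For each list, the balance of members with gained and lost loops and the median strength change were placed among 10000 random lists of protein-coding genes with as many loops. With 20 such percentiles per comparison, 1 outside the central 95% is expected by chance.

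Genes named in the text followed a rule fixed in the same way. Notch1, Tcf7 and Myc were always named. Per comparison and direction, up to 12 list genes with a particular loop were named by the number of bin sizes that call it, then by observed over expected. The 6 particular loops of any protein-coding gene with the most bin sizes, and the 4 shared loops with the largest strength change whose interval excluded 0, were added. Loops named for the number of bin sizes are selected for it. The results of some genes that this rule names are not reported here.

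The matching and interval steps were tested on simulated data made from the control list of 11736 loops. Of 200 loops left out, 98.5% were found absent. Of loops raised 1.5-fold and 2-fold, 77.8% and 98.0% had an interval above 0, against 3.92% of unchanged loops outside 0 in either direction. Of 200 boundaries left out, 85.5% were found absent. Other bin sizes, distances, thresholds, expected values and gene windows were tried as alternatives. Motifs in loop anchors were not analysed here, as no genome sequence was used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.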

Results

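Chromatin contacts were measured by in situ Hi-C in lineage-negative, Sca1-positive, cKit-positive (LSK) bone marrow cells, the compartment of mice that holds haematopoietic stem cells and multipotent progenitors. The 6 samples fell into 3 conditions of 2 samples each. Control LSK cells (NOTCHWT_TCFWT) carried no transgene. LSK cells with induced Notch1 signalling (NICD_TCFWT, called NICD here) expressed the Notch1 intracellular domain, the active form of the receptor, from the Rosa26 locus after Mx1-Cre recombination. The 2 remaining samples (NICD_TCFKO, called NICD/Tcf7-KO here) carried the same allele together with floxed Tcf7, the gene of the T-cell transcription factor TCF1. The lists analysed held chromatin loops and contact domains called once per condition with the replicates combined. No value per replicate was therefore at hand, no difference below has a replicate check, and no p-value between conditions is given. Intervals are 95% intervals, exact for counts and shares and from resampling loops for medians. They cover counting error or sampling of loops only, not variation between animals. Depth per library was stated only as a target common to every sample, and map depth was compared through the expected contacts at loops shared by 2 conditions. These were 0.826 times as many in NICD as in control, 1.18 times as many in NICD/Tcf7-KO as in NICD, and 0.969 times as many in NICD/Tcf7-KO as in control.

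Tcf7, the gene deleted in the third condition, had the same loop in all 3 conditions, from its end on chromosome 11 (52250001 to 52260000) to 52340001 to 52350000. It held 352 contacts in control, 321 in NICD and 400 in NICD/Tcf7-KO, which was 4.60, 4.58 and 4.80 times the local expectation. Lists of this resolution do not show the deleted exons, so they check neither the Tcf7 deletion nor the activity of Notch1. A loop of Notch1 on chromosome 2, from 26450001 to 26460000 to 26560001 to 26570000, held 260 contacts in NICD and 308 in NICD/Tcf7-KO. These were 4.58 and 4.52 times the local expectation. The loop was called within 20 kb in 22 bin sizes of control, 22 of NICD and 21 of NICD/Tcf7-KO. Myc, a proliferation gene that Notch1 activates in T cells, contacted 3 sites 1610 to 1740 kb to the right on chromosome 15 in all 3 conditions. The strongest of these loops joined 61980001 to 61990000 with 63650001 to 63660000. It held 145 contacts in control (6.12 times expected, 95% interval 5.16 to 7.20), 135 in NICD (7.03 times, 5.89 to 8.32) and 154 in NICD/Tcf7-KO (7.30 times, 6.19 to 8.55).

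**Figure D1:**
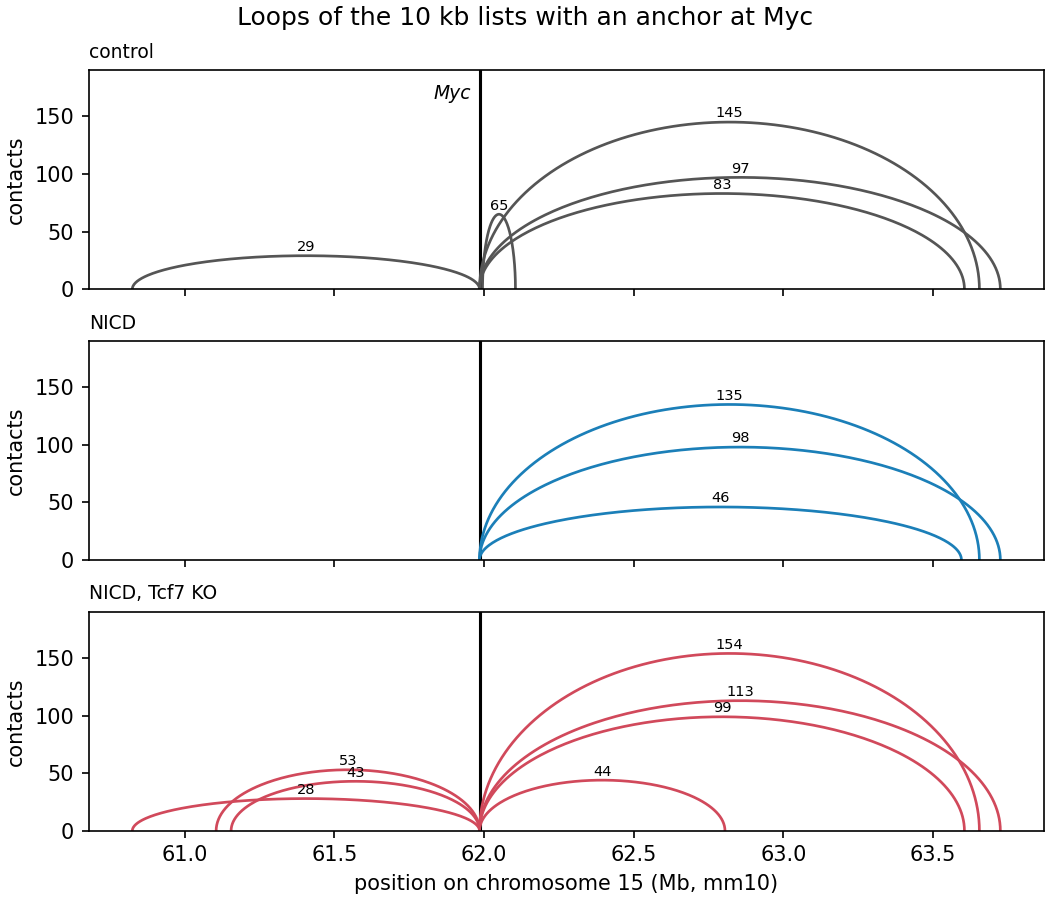
Loops of the 10 kb lists with an anchor at Myc in the 3 conditions, drawn as arcs over chromosome 15 (x axis, Mb, mm10), with the height of each arc giving its observed contacts (y axis). The 3 loops spanning 1610 to 1740 kb to the right were present in every condition, and 5, 3 and 7 loops touched Myc in control, NICD and NICD/Tcf7-KO. These counts are of the 10 kb lists alone. NICD called the loops with far anchors at 60820001, 61100001, 61150001 and 62800001 in 8, 2, 11 and 4 of all bin sizes. The control loop to 62100001 was called in 0 NICD bin sizes.

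The 3 conditions held loops of similar number and span. At 10 kb bins 11736 loops were called in control, 10938 in NICD and 11619 in NICD/Tcf7-KO. NICD had the fewest loops in all 22 of the bin sizes, while control had the most in 18 and NICD/Tcf7-KO in 4. Median loop span was 200 kb in control (quartiles 100 and 380 kb), 190 kb in NICD (100 and 370 kb) and 180 kb in NICD/Tcf7-KO (100 and 370 kb). Loops over 1 Mb made up 5.46% of the control list (5.06 to 5.89), 5.01% of the NICD list (4.61 to 5.44) and 4.91% of the NICD/Tcf7-KO list (4.52 to 5.31). A median of 88 contacts lay at a control loop, 80 at a NICD loop and 91 at a NICD/Tcf7-KO loop.

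**Figure D2:**
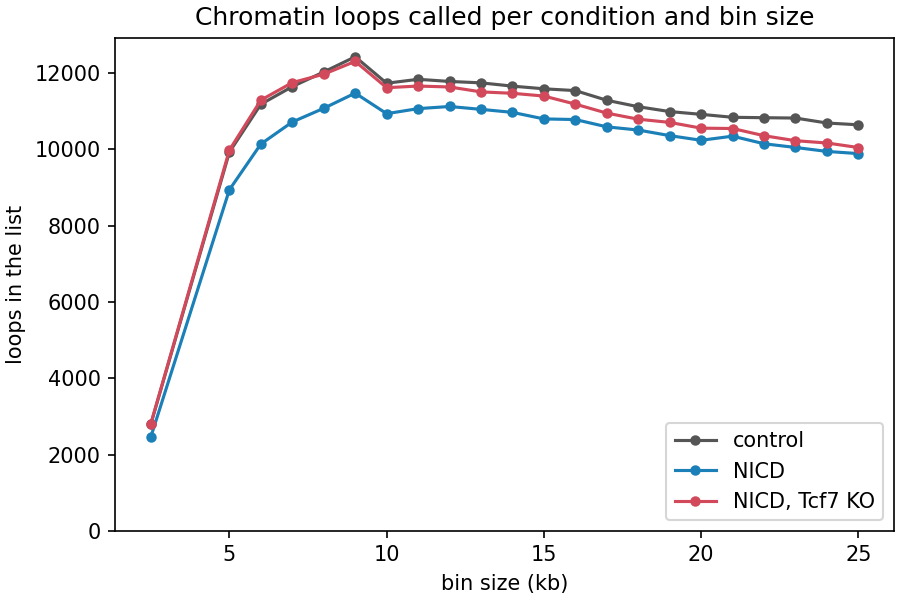
Number of loops in each list (y axis) against its bin size in kb (x axis), with a line per condition. NICD had the fewest loops at each of the 22 bin sizes, from 2460 at 2.5 kb to 11477 at 9 kb.

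The first comparison asked which contacts of LSK cells differed under Notch1 activation. Most loops were common to NICD and control, and the loops called in 1 condition alone were spread over many gene groups. Of the Notch target genes, Hes1 had loops particular to either condition, Notch1 had a loop particular to NICD, and Dtx1 and Myc had loops particular to control. The NICD loops of Hes1 and Notch1 were each called in only 1 bin size, and the control loops of Dtx1 and Myc in few. The B-lineage regulator Ebf1 had a contact in NICD that 16 bin sizes called and no control list held, and the T-lineage regulator Gata3 had a control contact that no NICD list held.

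Of the NICD loops 8512 (77.8%, 77.0 to 78.6) had a control loop within 20 kb at both anchors, and 8519 of the control loops (72.6%, 71.8 to 73.4) had a NICD loop. Lists shifted along the chromosomes gave 1.52% on average and 1.88% at most. For reference, 81.0% of NICD loops and 81.0% of control loops were found again within the same condition at 9 kb bins, and 79.9% and 79.0% at 11 kb bins. With both the condition and the bin size changed, 76.1% of NICD loops were found in control and 70.4% of control loops in NICD at 9 kb bins. Within a condition, matches were 61.1% to 62.8% at 5 kb bins, so there bin size alone moved calls more than condition did. At 25 kb bins they were 47.2% to 48.6%. The 25 kb lists hold no loop under 125 kb, while the lower quartile of 10 kb loop spans was 100 kb. This lower share is thus in part fixed by the bin size. When all 22 bin sizes of the other condition were searched, 567 NICD loops (5.18%) were absent from control, and 882 control loops (7.52%) were absent from NICD. Such loops were called in few lists of their own condition, a median of 4 bin sizes for NICD and 5 for control, against 16 for the other loops. Only 243 of the NICD loops and 451 of the control loops were called in at least 5 bin sizes.

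Among 10 gene lists chosen before the data were examined, none had a balance of gained and lost loops outside the central 95% of random lists with as many loops. Loops at gene ends that were particular to NICD touched 2 of 18 Notch targets, 1 of 30 T-lineage genes, 2 of 31 stem and progenitor genes and 1 of 21 myeloid and erythroid-megakaryocyte genes. They also touched 2 of 13 B-lineage genes, 0 of 15 Wnt pathway genes, 2 of 21 cell cycle genes, 2 of 20 T-cell leukaemia genes, 2 of 14 chromatin architecture genes and 0 of 16 interferon response genes. Loops particular to control touched 3, 2, 3, 0, 1, 2, 3, 4, 1 and 1 genes of these lists in the same order. The 3 stem and progenitor genes were the neighbours Hoxa7, Hoxa9 and Hoxa10, so 1 locus counts as 3 genes, and the random lists were not matched for such neighbours. The net balance of the Notch targets lay at percentile 43.6 of random lists and that of the T-lineage genes at percentile 46.8.

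In NICD the best supported gain at a list gene joined a site beside the right-hand end of Ebf1 on chromosome 11 (45010001 to 45020000) to 45880001 to 45890000, with 21 contacts, 5.03 times expected (3.11 to 7.69). This loop was called in 0 bin sizes of control, 16 of NICD and 9 of NICD/Tcf7-KO. Runx1 and Erg, transcription factors of stem cells, had loops of 330 and 590 kb in 8 and 7 NICD bin sizes, and NICD/Tcf7-KO also called them in 10 and 2. Pds5b, a cohesin regulator, had a NICD loop in 7 bin sizes. Ccna2, Satb1, E2f3, Notch1 and Hes1 had gains that 3, 3, 2, 1 and 1 NICD bin sizes called. The Hes1 gain of 70 kb lay within 50 kb of a loop that control called in 22 bin sizes. Outside the lists, the gains in the most bin sizes touched Bcas3 (19), Relch (18), Fkbp11 (17), Spry2 (17) and Megf11 (17). The Spry2 loop, at a feedback inhibitor of receptor tyrosine kinase signalling, spanned 720 kb with 33 contacts, 5.67 times expected (3.90 to 7.97), and was in no NICD/Tcf7-KO list.

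Control loops absent from NICD were led at list genes by Hes1, a direct Notch target. This loop joined 28910001 to 28920000 with 30060001 to 30070000 on chromosome 16, with 19 contacts, 8.64 times expected (5.20 to 13.5). It was called in 12 control bin sizes and in none of NICD or NICD/Tcf7-KO. Cd3g, of the T-cell receptor complex, had a loop with 98 contacts in 11 control bin sizes, but NICD called a loop within 50 kb in 16. The loop of the cohesin gene Smc1a, in 10 control bin sizes, likewise had a NICD loop within 50 kb in 9. Gata3 had a loop of 270 kb from 9880001 to 9890000 to 10150001 to 10160000 on chromosome 2, with 36 contacts, in 8 control bin sizes. Cdkn1b, an inhibitor of the cell cycle, had a loop of 2010 kb in 9 control and 12 NICD/Tcf7-KO bin sizes. Fzd6, Myc, the Hoxa7, Hoxa9 and Hoxa10 group, Dtx1 and E2f2 had loops in 5, 3, 2, 2 and 2 control bin sizes. Of all genes, Zfp277, Steap3, Tmem14a, Yipf5 and Ptch1 had lost loops called in 19 control bin sizes each. A loop of Myl12b spanned 31120 kb over a donut expectation of 0.0925 contacts, below 1, so its enrichment has little meaning.

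Loop strength, the observed over the donut-expected contacts, differed little between NICD and control. Over 8406 shared loops the median log2 change was 0.043 (0.037 to 0.048, resampling loops). Its SD was 0.235, and Poisson counts without any change gave 0.235, while with the lower-left expectation the SD was 0.251 against 0.235. The counting interval excluded 0 in 366 loops that were stronger in NICD and in 166 that were weaker, against 177 and 177 in simulated unchanged lists. At the 6202 loops called in the same pixel of both lists the interval counts were 195 stronger and 64 weaker, against 132 and 131. Of these loops 53 were more than 1.5-fold stronger and 15 more than 1.5-fold weaker, against 58 and 67 by chance. Their median log2 change was 0.040, and their SD was 0.204 against 0.227 from counting. The simulated lists hold no such shift, which alone moves calls from weaker to stronger. These counts thus do not show single stronger loops beyond a small common shift. The folds named below and in the next comparisons set loops within 20 kb against each other, and only 5 of these 24 lay in the same pixel, so most go with a shift of the called position. Among loops at genes, those of the interferon-inducible gene Ifi203 on chromosome 1 were 2.40-fold and 2.24-fold stronger in NICD, with 54 against 58 and 34 against 41 contacts, so that the expected rather than the observed value differed. The same held for Gm13212 (2.23-fold, 19 against 17 contacts) and Acta2 (2.15-fold, 87 against 85 contacts). Loops at Ilk (0.388-fold, 96 against 251 contacts), Sh2b2 (0.488-fold, 226 against 264), Rgs3 (0.506-fold, 175 against 288) and D630039A03Rik (0.520-fold, 55 against 64) were weaker. For Sh2b2 and D630039A03Rik it was mainly the expected value that differed, 84.4 against 48.1 and 18.4 against 11.1.

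**Figure D3:**
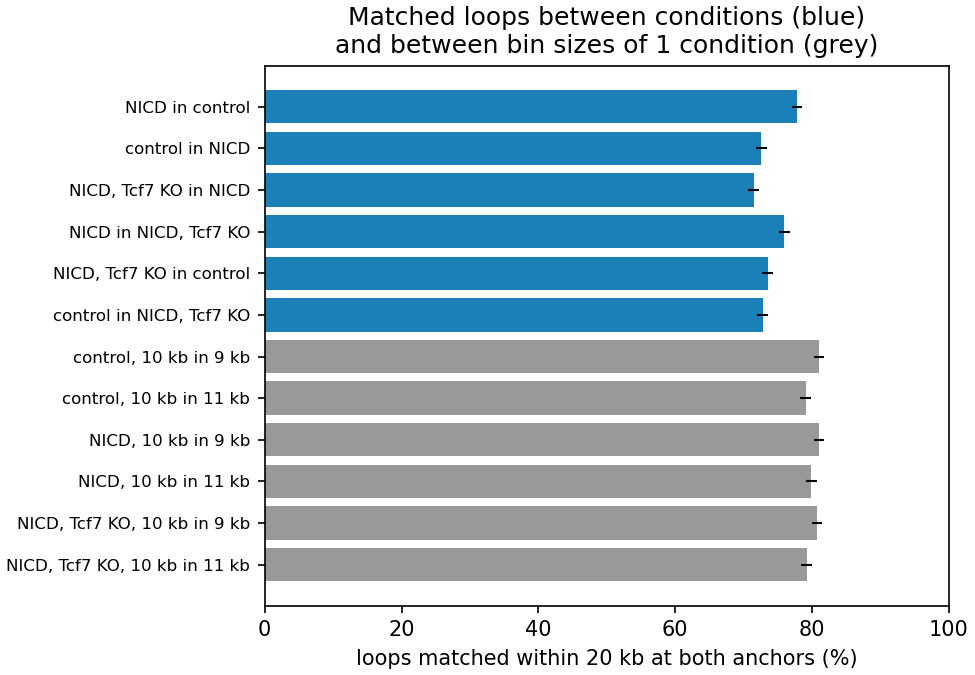
Percent of the loops of a 10 kb list that had a loop within 20 kb at both anchors (x axis), in the list of another condition (blue) or in the 9 or 11 kb list of the same condition (grey), with exact 95% intervals. Matches between conditions lay between 71.5% and 77.8%, and those between bin sizes of the same condition between 79.0% and 81.0%.

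The second comparison asked which contacts of Notch1-activated LSK cells depended on Tcf7. Most loops were common to both conditions, and no gene list stood apart from random lists at 10 kb bins. The Notch ligand gene Jag1 had a NICD/Tcf7-KO contact of 620 kb in 17 bin sizes, and Smc3, a cohesin subunit gene, one in 15, and no NICD list held either. Gata2, a transcription factor of stem cells, had a NICD loop in 13 bin sizes that no NICD/Tcf7-KO list held. Control called that loop too.

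Of the NICD/Tcf7-KO loops 8307 (71.5%, 70.7 to 72.3) matched a NICD loop, and 8307 NICD loops (75.9%, 75.1 to 76.7) matched in return, against 1.46% under shifting. After all bin sizes were searched, 966 NICD/Tcf7-KO loops (8.31%) were absent from NICD and 762 NICD loops (6.97%) were absent from NICD/Tcf7-KO. Of these, 534 and 416 were called in at least 5 bin sizes. No list passed the central 95% of random lists. The T-lineage balance lay highest, with 4 gained (Gata3, Lef1, Cd28 and Tox) against 0 lost of 30 at percentile 96.7, followed by that of the cell cycle genes at 94.2. With gene ends inside the anchor the T-lineage balance was 1 against 0 (percentile 72.4), and at 25 kb bins 4 against 2 (81.3). NICD/Tcf7-KO loops absent from NICD touched 3 Notch targets, 4 T-lineage genes, 2 stem and progenitor genes, 1 myeloid or erythroid-megakaryocyte gene and 0 B-lineage genes. They touched 1 Wnt pathway gene, 5 cell cycle genes, 1 T-cell leukaemia gene, 2 chromatin architecture genes and 2 interferon response genes. NICD loops absent from NICD/Tcf7-KO touched 1, 0, 2, 1, 1, 0, 2, 3, 4 and 0 genes in that order.

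The Jag1 loop of NICD/Tcf7-KO joined 137110001 to 137120000 with 137730001 to 137740000 on chromosome 2, with 38 contacts, 2.57 times expected (1.82 to 3.52), and no list of the other conditions held it. The Smc3 loop spanned 90 kb with 83 contacts, 2.67 times expected (2.12 to 3.30), and control called it in 4 bin sizes. Pds5b had a NICD/Tcf7-KO loop of 220 kb in 11 bin sizes. Etv6 and Mllt3, genes of leukaemia fusions, had loops in 8 and 6 bin sizes, and Gata3 one of 60 kb in 6. Ifit2 and Lfng had loops in 5 bin sizes each, and Cdk1 and Lef1 in 4 each. Those of Lfng and Cdk1 had a NICD loop within 50 kb in 2 and 15 bin sizes. Of all genes, a 470 kb loop at Vps13b was called in all 22 NICD/Tcf7-KO bin sizes and in none of either other condition. It joined 35450001 to 35460000 with 35920001 to 35930000 on chromosome 15, with 133 contacts, 4.92 times expected (4.12 to 5.84). Loops at Mmadhc, Gm51464 and Mrgprx1 were called in 21 bin sizes of NICD/Tcf7-KO alone, the last 2 both near 48 Mb on chromosome 7. Neto2 and L3hypdh had loops in 20 and 18 NICD/Tcf7-KO bin sizes, and in 8 and 12 of control.

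The NICD loop of Gata2 that NICD/Tcf7-KO lacked joined 88180001 to 88190000 with 88480001 to 88490000 on chromosome 6, with 64 contacts, 2.48 times expected (1.91 to 3.17). Smc1a, Pds5b, Cdkn1b and Wapl had such loops in 9, 7, 7 and 7 NICD bin sizes, and Stag2, E2f3, Tal1, Ezh2 and Notch1 in 5, 2, 2, 2 and 1. Those of Gata2, Smc1a, Cdkn1b, Wapl, Stag2, Tal1 and Ezh2 were also called in control, so they were not gains of NICD. Smc1a and Stag2, which encode cohesin subunits, lie on chromosome X. The Wapl and Stag2 loops had a NICD/Tcf7-KO loop within 50 kb in 3 and 9 bin sizes. Of all genes, an Igfbp5 loop of 400 kb (58 contacts, 4.79 times expected, 3.64 to 6.20) was in 21 NICD and 20 control bin sizes. Ang4, Gm5885, Skint6 and Cyp2b9 had such loops in 20 NICD bin sizes each. A Dnah7a loop spanned 7300 kb over a donut expectation of 0.110 contacts.

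At 8186 shared loops the median log2 strength change from NICD to NICD/Tcf7-KO was 0.0010 (-0.0041 to 0.0071), with an SD of 0.245 against 0.231 from counting alone. Intervals excluded 0 in 307 loops that were stronger and 273 that were weaker in NICD/Tcf7-KO, against 172 and 173 by chance. In the same pixel the interval counts were 152 and 142, against 127 and 127, and 26 of 6023 loops were more than 1.5-fold stronger and 55 weaker, against 58 and 53 by chance. The SD of these loops was 0.214 against 0.224 from counting, while the interval counts were above chance in both directions. Loops called in the same pixel are selected for agreement between the lists, and the simulated counts scattered more than the data. This SD thus cannot exclude spread beyond counting. The stronger loops were led by Gm51877 (2.81-fold, over 0.0327 expected contacts), Dnhd1 (2.17-fold), Pcm1 (2.15-fold) and Slain1 (2.15-fold, 211 against 168 contacts). That of Gm51877 spanned 105820 kb, and with an expectation below 1 its fold has little meaning. The weaker loops were led by Mptx2 (0.449-fold, 37 against 91 contacts), Trpa1 (0.473-fold), Opn3 (0.492-fold) and Lipa (0.496-fold). Mptx2, Trpa1 and Opn3 lie on chromosome 1, and of the 8 loops named here those of Gm51877, Mptx2 and Opn3 were in the same pixel. The Dnhd1 and Lipa loops were compared with the same NICD loops as Ilk and Acta2 above, so a single NICD value enters both comparisons.

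The third comparison set NICD/Tcf7-KO against control. Myc had a contact at 61100001 to 61110000 that 17 NICD/Tcf7-KO bin sizes called, against 2 of NICD and 0 of control. Cell cycle genes were touched more often by loops particular to NICD/Tcf7-KO, 6 of 21 against 2, with Ccnd1, Ccnd3, Ccne2, Cdk4, Cdkn1b and Mki67 in the first group and Cdkn1b and E2f2 in the second. This balance lay at percentile 99.1 of random lists. The balance lay at percentile 91.7 with gene ends inside the anchor and turned to 5 against 9 genes at 25 kb bins (percentile 14.2). Bcl11b, a T-lineage commitment factor, had a control loop of 1030 kb in 8 bin sizes that no NICD/Tcf7-KO list held.

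Matches were found for 8540 of the NICD/Tcf7-KO loops (73.5%, 72.7 to 74.3) and 8539 of the control loops (72.8%, 71.9 to 73.6), against 1.52% under shifting. Absent from every list of the other condition were 941 NICD/Tcf7-KO loops (8.10%) and 1000 control loops (8.52%), of which 523 and 593 were called in at least 5 bin sizes. NICD/Tcf7-KO loops touched 4 Notch targets, 4 T-lineage genes, 2 stem and progenitor genes, 0 myeloid or erythroid-megakaryocyte genes and 0 B-lineage genes. They touched 3 Wnt pathway genes, 2 T-cell leukaemia genes, 1 chromatin architecture gene and 3 interferon response genes. Control loops touched 2, 3, 4, 0, 1, 1, 4, 3 and 1 genes of these 9 lists. The 4 stem and progenitor genes were Tal1 and the neighbours Hoxa7, Hoxa9 and Hoxa10.

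The gained Myc loop held 53 contacts, 3.84 times expected (2.87 to 5.02), over 880 kb, and control called a loop within 50 kb of it in 1 bin size. A neighbouring Myc loop of 830 kb, with its far anchor at 61150001 to 61160000, was called in 9 control, 11 NICD and 10 NICD/Tcf7-KO bin sizes. Ddx58, an RNA sensor of the interferon response, Bcl2, Ccnd1 and Cdk4 had gains in 10, 7, 6 and 5 NICD/Tcf7-KO bin sizes. That of Ddx58 had a control loop within 50 kb in 19 bin sizes. Jag1, Pds5b, Mllt3, Gata3 and Ifit2 had the gains given above. Cdkn1b had another gain of 1880 kb in 6 bin sizes. Cnot10 and Kif15 had loops in 21 NICD/Tcf7-KO bin sizes, with 9 and 8 of NICD, and Vps13b, Mmadhc, Gm51464 and Mrgprx1 led this comparison too. Control loops absent from NICD/Tcf7-KO were led by Stag2 (15 bin sizes), Hes1 (12), Cd3g (11), Wapl (11) and Smc1a (10). Those of Stag2, Cd3g and Wapl had a NICD/Tcf7-KO loop within 50 kb in 9, 10 and 3 bin sizes. The Bcl11b loop joined 106960001 to 106970000 with 107990001 to 108000000 on chromosome 12, with 29 contacts, 3.47 times expected (2.32 to 4.98), and NICD called it in 2. Gata3, Fzd6, Tal1, Cdkn1b, Hoxa10 and Hoxa7 followed with 8, 5, 4, 4, 2 and 2 control bin sizes. Of all genes, Dnah7a and Gm17434 led in 21 control bin sizes over expectations below 1, and Skint5, Cyp2b9, Tagln and Igfbp5 followed in 20.

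At 8435 shared loops NICD/Tcf7-KO was stronger by a median log2 of 0.037 (0.031 to 0.043), with an SD of 0.248 against 0.226 from counting. Intervals excluded 0 in 507 stronger and 241 weaker loops, against 179 and 177 by chance. In the same pixel the interval counts were 283 and 107, against 132 and 131, and 43 of 6200 loops were more than 1.5-fold stronger and 31 weaker, against 50 and 53 by chance. The SD of these loops was 0.213 against 0.219 from counting. Here too the simulated counts scattered more than the data, so this SD cannot exclude spread beyond counting. Interval counts were above chance for stronger loops only, and whether the common shift alone gives this excess was not tested. Gm51877 (2.84-fold), Serpina9 (2.49-fold), Mthfs (2.32-fold) and Pcm1 (2.31-fold) led the stronger loops. That of Gm51877 spanned 105820 kb over a donut expectation of 0.0327 contacts, below 1, so its fold has little meaning. D630039A03Rik (0.398-fold), Cxcl14 (0.422-fold, 93 against 169 contacts), Mptx2 (0.453-fold, 37 against 101 contacts) and Tbr1 (0.483-fold) led the weaker, and those of Gm51877 and Mptx2 were in the same pixel.

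To ask whether Tcf7 loss undid the Notch1-induced changes, the 3 conditions were set side by side. Of 16161 distinct loops of the 10 kb lists 12870 (79.6%) were called in all 3 conditions when each condition was searched at all bin sizes. NICD alone held 297, NICD/Tcf7-KO alone 550 and control alone 496. Loops shared by NICD and NICD/Tcf7-KO but absent from control numbered 553, those of control and NICD alone 749, and those of control and NICD/Tcf7-KO alone 646. Of 850 loops of any 10 kb list that NICD held at some bin size and control at none, 297 (34.9%, 31.7 to 38.3) were missing in NICD/Tcf7-KO, against 5.50% of the loops common to control and NICD and 13.7% of such loops called in as many bin sizes. The same share was 49.9% for loops gained in NICD/Tcf7-KO over control that NICD lacked, against 11.7% of matched common loops, so that this loss was not particular to NICD gains.

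At 7247 loops called in all 3 conditions, the strength change from control to NICD and that from NICD to NICD/Tcf7-KO had a correlation across loops of -0.46. Loops are not independent replicates, and both changes share the NICD counts, which gave -0.54 in simulations without any change. The covariance was -0.0266, against -0.0278 simulated, a difference of 0.0012. With NICD/Tcf7-KO as the shared condition the difference was -0.0101, and with control -0.0063. In the same pixel the simulated counts scattered more than the data, with an SD of 0.227 against 0.204 for control and NICD. For NICD and NICD/Tcf7-KO it was 0.224 against 0.214. An opposite change after Tcf7 loss was thus not detected in loop strength. As the simulated values lay beyond the observed ones, the comparison cannot exclude such a change.

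Contact domains followed the order of the loops only in part. Control had 4602 domains, NICD 3961 and NICD/Tcf7-KO 4678, with a median size of 135 kb in each. Of the NICD domain boundaries 86.6% (85.8 to 87.4) lay within 25 kb of a control boundary, against 15.3% under shifting. In the reverse direction, 77.9% of control boundaries matched NICD. NICD/Tcf7-KO boundaries matched NICD in 76.5% (75.6 to 77.4), and NICD boundaries matched NICD/Tcf7-KO in 86.4%. Between NICD/Tcf7-KO and control the shares were 81.7% (80.8 to 82.5) and 82.6%. The shares move with list length, and NICD boundaries were found about equally often in either other condition. Both ends matched for 78.9% of NICD domains in control and 78.6% in NICD/Tcf7-KO, for 67.9% of control domains and 66.6% of NICD/Tcf7-KO domains in NICD, and for 71.9% of NICD/Tcf7-KO domains in control and 73.1% in reverse.

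Chromosome X differed from the autosomes, most in NICD/Tcf7-KO. Relative to the autosomes, contacts at shared X loops were higher by a log2 of 0.16 (0.13 to 0.20, resampling loops) than in control and by 0.087 (0.041 to 0.14) than in NICD. NICD exceeded control by 0.040 (0.0063 to 0.085), where the autosomes lay between -0.023 and 0.028. The autosomes of the widest comparison, NICD/Tcf7-KO against control, lay between -0.049 and 0.027. X loops were weaker in NICD/Tcf7-KO by a median log2 of -0.19 against NICD and -0.16 against control. The change on X from control to NICD was -0.0055, also below the autosomes, which lay between 0.031 and 0.060. Loops on chromosome Y appeared in 9 control lists, 13 NICD lists and 0 NICD/Tcf7-KO lists. Smc1a and Stag2, named above, lie on this chromosome.

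**Figure D4:**
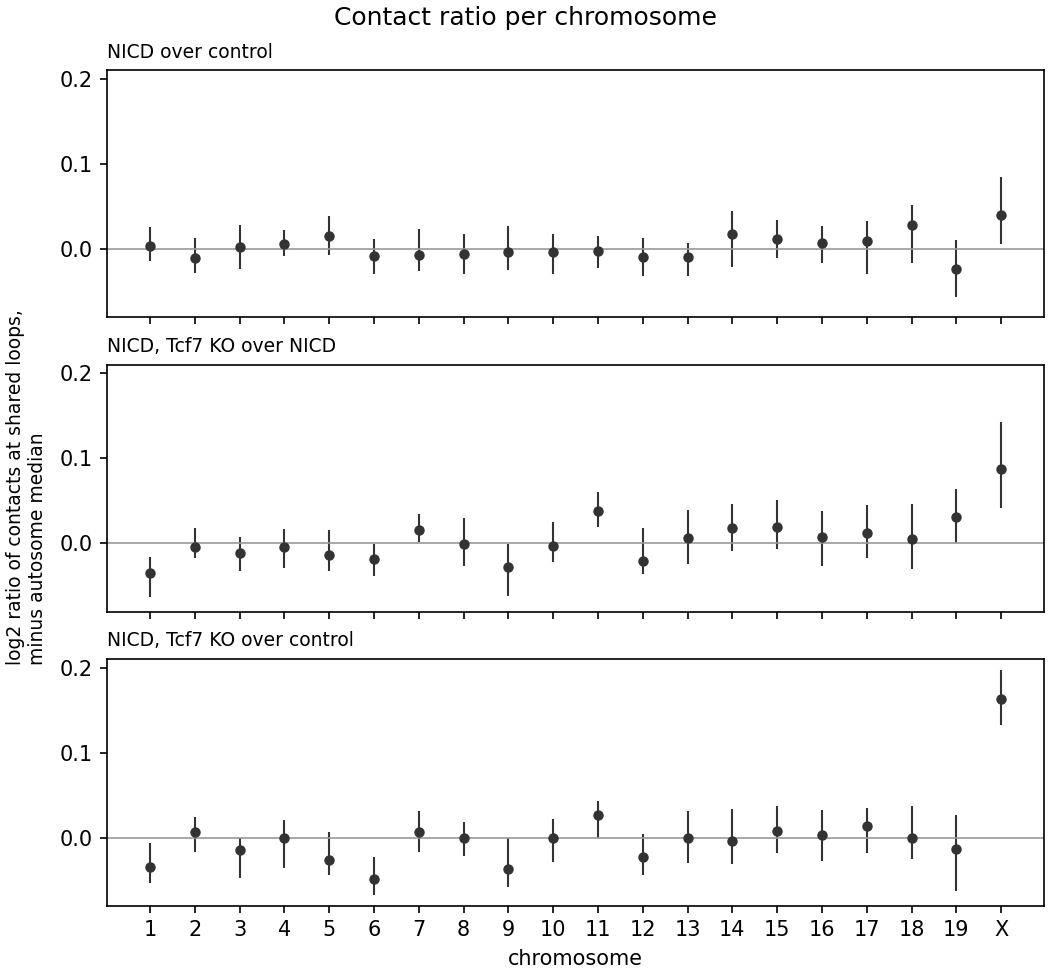
Median log2 ratio of observed contacts at shared loops per chromosome, minus the autosome median (y axis), for the 3 comparisons, with 95% intervals from resampling loops. Chromosome X lay at 0.16 in NICD/Tcf7-KO over control, above every autosome.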

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

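Loops over 5 Mb or of near-zero expectation, chromosome X, support in 10 bin sizes and matching by pixel were examined only after the data were seen; the other alternatives were fixed beforehand. No paired analysis was possible because the lists pool the replicates of a condition, and for the same reason no replicate was left out. Motif content of anchors was not run. Under the alternatives, 75 values of the main results stayed within the interval or 1.5 times the count and 68 moved, and for single genes, loops and lists 265 stayed, 24 moved and 1 reversed. The 265 include 103 named loops at an anchor distance of 10 kb, which could not move, as they were chosen for absence within 20 kb. Strength changes and X contacts whose interval left out 0 in the main setting kept their sign, while the strength change from NICD to NICD/Tcf7-KO and the covariance beyond counting, both near 0, took either sign. The reversed value was the cell cycle balance of NICD/Tcf7-KO against control, 4 in the main setting and -4 at 25 kb, and the cause was not tested. NICD had the fewest loops in the 5 and 25 kb lists, under the stricter threshold (donut q at most 0.001 and observed at least 2 times expected) and without very long loops. Where values below moved, the cause was not tested, except that a looser or tighter distance, threshold or support changes what is counted. Loop lists limit what can be seen to contacts past the callers' thresholds, so a missing call at the lower NICD depth is not a missing contact.

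For control, NICD and NICD/Tcf7-KO, loops over 1 Mb made up 2.39%, 2.34% and 2.23% at 5 kb and 27.2%, 23.4% and 23.7% at 25 kb. Matches of NICD in control were 76.1% at 5 kb, 75.1% at 25 kb, 79.0% under the stricter threshold, 74.2% within 10 kb, 82.4% within 50 kb and 74.4% with equal numbers of loops. Those of NICD/Tcf7-KO in NICD were 66.9% at 5 kb, 67.8% within 10 kb, 76.5% within 50 kb and 73.6% with equal numbers. Those of NICD/Tcf7-KO in control were 70.4% at 5 kb, 71.2% at 25 kb, 74.4% under the stricter threshold, 70.2% within 10 kb and 78.6% within 50 kb.

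Loops absent from the other condition were counted in the order NICD and control, NICD/Tcf7-KO and NICD, NICD/Tcf7-KO and control. Against the 10 kb list alone they numbered 2426 and 3217, 3312 and 2631, 3079 and 3197. Those in at least 5 bin sizes numbered 243 and 451, 534 and 416, 523 and 593, and those in at least 10 numbered 70 and 156, 193 and 192, 204 and 269. Within 50 kb, NICD loops absent from control numbered 376. At that distance 16 of 103 named loops were called in the condition that lacked them. At 10 kb 0 were, which was fixed in advance, as these loops were chosen for absence within 20 kb.

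The median log2 strength change of NICD over control was 0.066 at 5 kb, 0.028 at 25 kb and 0.037 with the lower-left expectation. That of NICD/Tcf7-KO over NICD, not distinct from 0 in the main setting, was -0.034 at 5 kb, 0.013 at 25 kb and -0.013 with the lower-left expectation. That of NICD/Tcf7-KO over control was 0.031 at 5 kb and 0.027 with the lower-left expectation. NICD gains missing in NICD/Tcf7-KO came to 40.9% at 5 kb and 53.0% at 25 kb. The covariance beyond counting was -0.0019 with the lower-left expectation and 0.0063 at 5 kb. The X excess of NICD/Tcf7-KO over NICD was 0.14 at 25 kb.

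With corner scores at or above the median, domains numbered 2266 in control, 1954 in NICD and 2401 in NICD/Tcf7-KO. Boundary matches of NICD in control were 77.0% within 10 kb, 91.6% within 50 kb and 87.8% under the stricter score. Those of NICD/Tcf7-KO in NICD were 66.3%, 82.3% and 74.7%, and in control 71.1%, 87.1% and 80.2%. Of 20 list percentiles, those outside the central 95% for NICD against control numbered 1 with gene ends inside the anchor and 3 at 25 kb, and for NICD/Tcf7-KO against NICD 1 at 25 kb. At 25 kb the balance of the B-lineage genes was 3 in the first (percentile 98.6) and -4 in the second (percentile 1.15), opposite directions that the 10 kb setting (1 and -1) did not place outside; both use the same NICD list. Also outside at 25 kb in the first were the interferon response balance of -4 (percentile 2.03) and the strength of chromatin architecture genes (percentile 1.51). For NICD/Tcf7-KO against control there was 1 in the main setting and 1 in each of these alternatives, where 1 is expected by chance. They were different lists or measures: the stem and progenitor genes had stronger shared loops with gene ends inside the anchor (percentile 99.9), and the cell cycle genes weaker ones at 25 kb (percentile 0.67).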

Other observations

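Pds5b, a regulator of cohesin, had a NICD loop of 560 kb in 7 bin sizes and a separate NICD/Tcf7-KO loop of 220 kb in 11, and control called neither. Gata3 likewise had different loops in different conditions, one of 270 kb to the right in 8 control bin sizes and one of 60 kb to the left in 6 NICD/Tcf7-KO bin sizes, and NICD called neither. These 2 genes were singled out after their values were seen.

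The tests of gene families, of clustering, of contacts on X and of strength on X were chosen after their patterns were seen, and those of depth and of domains on X before. NICD had the fewest loops in every list and also the lowest map depth. When control and NICD/Tcf7-KO counts were scaled to the NICD depth and held to the lowest counts and enrichments of listed loops, 11378 and 11101 loops were left. The higher of these is 104% of the NICD number, within the 5% set beforehand, so lower depth is a candidate explanation for the shortfall. With counts thinned at random the numbers were 102% and 100.2% of the NICD number. The sort gate and a biological effect of Notch1 activation on loop number stay open and were not tested.

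In NICD/Tcf7-KO, contacts on X exceeded those of control by a log2 of 0.16 relative to autosomes and no chromosome Y loop was called, which is consistent with more females among the pooled NICD/Tcf7-KO animals, whose sex the labels used here do not give. The strength change on X against NICD, -0.19, lay outside the autosome range of -0.022 to 0.030, which restates that X stands apart and tests no explanation. More inactive X chromosomes could weaken X loops, but the share of domains on X, 1.58% (1.24 to 1.98) against 1.59% in control and 1.49% in NICD, did not decide it; the reading of this test was corrected after its value was seen, and the value is used for nothing. An effect of Tcf7 loss on X stays open as untested. Loops missing in NICD/Tcf7-KO but present in control and NICD lay on X in 4.27% of 749, against 2.59% of the loops of all 3 conditions.

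Several of the best supported differences lay at gene families, such as 4 of 6 neighbouring loops of NICD/Tcf7-KO alone in the Mrgpr region near 47 Mb of chromosome 7, and mixed strain haplotypes or shared reads could produce such calls. For the loops of 1 condition alone as a set this stays open, since they touched families 0.691 times as often (0.357 to 1.65, resampling both sets) as loops of all 3 conditions called in as many bin sizes, of which few were called in only 1. Without that matching they touched families in 4.39% against 4.08%, in 6.01% against 4.05% when called in at least 5 bin sizes, and in 6.75% against 4.15% in at least 10. Families were at least 5 genes within 500 kb with a shared symbol stem, and Zfp, Gm and some other stems were left out. Near 67 Mb of chromosome 13, among Zfp genes, 0 of 4 loops of NICD alone were counted as touching a family. Windows of 1 Mb with 3 or more loops of the same condition alone numbered 21, against a mean of 19.6 and up to 35 in 1000 random draws of other loops with as many bin sizes, so clustering beyond chance was not seen. No biological explanation was tested.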
